A study of Mus musculus with 18 samples.

How the data were processed

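Livers came from male mice 12 weeks old that had eaten the test diets for 8 weeks from the age of 4 weeks and were fasted for 4 h, per the labels' protocols. Each array carried a pool of RNA from 3 mice, so that 9 mice stand behind each group of 3 arrays, and siblings of a genotype were randomized between diets. The pool is the replicate throughout. Pooling averages out differences between mice, and the spread between pools mixes mice with handling. Sample labels give the diets 7% fat and the series text gives 6%.

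The values used are the deposited expression values of the Affymetrix Mouse Genome 430 2.0 array, made with RMA per the submitters' processing notes, which give no software version. That the deposited values are on a log2 scale was read from the values themselves, which run from 2.409 to 14.89 with array medians from 5.229 to 5.286. No array was normalized again in the main fit, no value was missing and 0 pairs of arrays were identical. Of 45101 probe sets 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed in the probe table used and stay unnamed. Symbols were updated by gene ID against the RefSeq table of mouse build GRCm38.p6, which matched 34741 probe sets. A gene was read from the probe set with the highest mean over all 18 arrays (9010 genes had more than 1). It was tested if that probe set lay above the array's median in at least 3 of the 18 arrays, which left 12578 of 18193 genes and set 5615 aside as dim. No probe set was named for Por, which is therefore not analysed here.

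Tests were made with limma 3.58.1 in R 4.3.3. One fit of 6 group means over all 18 arrays, with an intensity trend in the empirical Bayes step, gave every contrast and a shared estimate of the spread. P-values are two-sided, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The knockout effect was taken as the mean over the 3 diets, each weighted equally, and within each diet. Diets were compared in pairs within each genotype, and an F test on the interaction contrasts asked whether the knockout effect depends on the diet. Errors of log2 changes are standard errors from the fit, and group values are mean ± SD of 3 pools. Correlations of effects are Pearson's r across genes between contrasts that share no array. Their standard error comes from leaving out each array in turn.

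The design, the alternatives, the gene lists and the rule for naming genes were written before the data were examined. There were 33 lists, 22 of pathways and 11 of cell types, drawn up from textbook knowledge of liver metabolism. They were tested with camera at a preset correlation of 0.01 where at least 5 members were tested (30 lists). camera with a correlation estimated from the data, and fry, served as alternatives. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. Lists overlap: 19 of the 26 tested targets of CAR and PXR and 13 of the 31 P450s are in another list, as are 8 of the 26 genes of fatty acid synthesis and 7 of the 14 of desaturation and elongation. So are 7 of the 18 male-biased and 6 of the 14 female-biased genes. None of the 18 macrophage, 16 stellate or 14 endothelial markers is.

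The naming rule takes Por. For the averaged knockout effect and for fish/fungal oil against lard in each genotype, it takes the 10 largest rises and 10 largest falls among genes past the threshold whose arrays do not overlap between the groups (within each diet for the average). For the other contrasts it takes 3 and 3, and for the interaction the 10 smallest p of the F test. From each fixed list, in the averaged knockout effect and in fish/fungal oil against lard, it takes up to 4 members past the threshold, or up to 2 given as values where none passed. Groups of 3 fail to overlap by chance in 10% of genes. Genes outside the rule are said to have been named after their values were seen.

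Alternatives were repeated quantile normalization, centring each array on the median of the genes tested, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, no intensity trend, array weights, only the groups compared in the fit, a replicate block, and leaving out each array. Labels were also split anew in every balanced way the design allows, or in 100 draws including the real one. For the correlations of diet effects there were 34 draws including the real one. The scripts were tested on simulated values with 67, 67 and 66 genes planted at log2 changes of 0.5, 1 and 2 among 12578. The averaged knockout test then called 18 unchanged genes, and fish/fungal oil against lard in controls 14. A planted NRF2 list was found by all 3 list tests, and 0 other lists were. The simulated genes were drawn independently of each other. These simulations therefore cannot show false list calls that come from correlated genes.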

Results

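Gene expression was measured in livers of male mice that carry floxed P450 reductase alleles with the albumin-Cre transgene (knockout) or without it (control). The mice ate a diet made with lard, with canola oil or with a mixture of fish and fungal oils for 8 weeks, and RNA from 3 livers was pooled for each array. Each of the 6 groups of genotype and diet holds 3 pools, 18 arrays in all. Array medians lay between 5.229 and 5.286 on the log2 scale, and arrays of 1 group correlated at 0.99283 to 0.99691. Of 18193 named genes, 12578 were bright enough to test. A change from or to a group mean below the array medians is a lower bound in size. Por, the deleted gene, is not analysed here, so the genotype labels were not checked on their own target.

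The first question was what loss of hepatic P450 reductase does to liver expression whatever the diet, averaged over the 3 diets (9 pools per genotype). The largest rise was in Cyp2b10, the P450 classically induced through the nuclear receptor CAR (log2 change 4.91 ± 0.28 SE, 30.1-fold, adjusted p = 1.5e-08). Cyp2c55, an arachidonic acid hydroxylase also under CAR and PXR, rose by 4.14 ± 0.20 (17.6-fold, adjusted p = 1.2e-09), and the glutathione transferase gene Gstm3 by 3.04 ± 0.20 (8.23-fold, adjusted p = 9.1e-08). Nebl, which encodes an actin-binding protein, rose by 2.29 ± 0.17 (adjusted p = 3.6e-07). Lcn2, an iron-binding acute phase protein, rose by 1.97 ± 0.27 (adjusted p = 0.00045). The transporter gene Slco1a4 (1.63 ± 0.19, adjusted p = 0.00011), the protease inhibitor gene Serpinb1a (1.56 ± 0.20, adjusted p = 0.00028), the glucuronosyltransferase gene Ugt2b37 (1.43 ± 0.24, adjusted p = 0.002), the retinoic acid hydroxylase gene Cyp26a1 (1.42 ± 0.22, adjusted p = 0.0011) and the estrogen sulfotransferase gene Sult1e1 (1.41 ± 0.28, adjusted p = 0.0068) complete the 10 largest rises among genes whose arrays do not overlap between the genotypes within any diet. Of the called genes with overlap Mmp12 (1.61) and Asns (1.59), taken up below, rose more than the last 4 of these. Other probe sets of Cyp2b10 gave larger changes, 7.08 and 6.91, and the other probe set of Gstm3 gave 3.25. For Nebl, 2 dim probe sets gave -0.04 and 0.17. Control means of Nebl (3.95 to 4.15) and Sult1e1 (4.23 to 4.30) lay below the array medians, so their changes are lower bounds and their places among the 10 are uncertain.

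Falls were fewer and smaller. The largest were in genes whose arrays overlap between the genotypes in some diet: Enho (-1.56, adjusted p = 0.00477), Serpina4-ps1 (-1.49, 0.00735) and Obp2a (-1.27, 0.0012), named after their values were seen, and Serpina12 (-1.10, 0.0028). The knockout lard mean of Obp2a lay below the array medians, so its fall is a lower bound in size. Among genes without overlap Tmem120a, needed for fat cell differentiation, fell by 1.06 ± 0.15 (adjusted p = 0.00056), the endosomal sorting gene Snx17 by 0.74 ± 0.07 (adjusted p = 1.1e-05) and Cyp7b1, the oxysterol 7alpha-hydroxylase, by 0.63 ± 0.11 (adjusted p = 0.0034). The acetyltransferase gene Nat8f1 fell by 0.40 ± 0.09 (adjusted p = 0.016), Heatr1 by 0.35 ± 0.07 (0.0094), the phosphate transporter gene Slc17a2 by 0.30 ± 0.06 (0.0059) and S1pr5 by 0.29 ± 0.06 (0.0064). Tmem254a (-0.28, adjusted p = 0.012), Spin1 (-0.28, 0.01) and 0610005C13Rik (-0.27, 0.012) follow. With the mean of all probe sets of a gene, Heatr1 was at -0.09 (adjusted p = 0.27), Nat8f1 at -0.24 (0.063) and Spin1 at -0.20 (0.1), and none of the 3 passed. Dim probe sets of Heatr1 gave 0.12 and -0.05, and the other 3 of Spin1 gave -0.30, -0.13 and -0.10. In all, 575 genes passed the threshold, 480 higher and 95 lower in the knockout, and 573 of them had the same sign on all 3 diets. These genes were chosen by the mean of the same 3 effects, which favours equal signs, so the 573 do not test agreement between diets. At least 2-fold changes were seen in 27 of the higher and 5 of the lower genes, and 2262 genes had an unadjusted p under 0.05 against 629 by chance. Without knockout canola replicate 2 the count was 371. Repeating quantile normalization gave 400 higher and 163 lower genes, so the higher share was 71.0% instead of 83.5%. In a simulation of this comparison over 12578 genes, 89.6% of planted changes of log2 0.5 and 100% of those of log2 1 or 2 were found.

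Genes of xenobiotic metabolism held the largest changes. Of 26 tested targets of CAR and PXR, 17 rose and none fell (19 higher adjusted over the list alone; median log2 change 0.40, list adjusted p = 7.8e-28, and 0.0378 with an estimated correlation). They include the carboxylesterase gene Ces2a (1.06 ± 0.09, adjusted p = 1.2e-06). Among 31 P450s of families 1 to 3, 12 rose, with Cyp3a25 at 0.46 ± 0.04 and Cyp3a11 at 0.38 ± 0.04 (both adjusted p = 6.9e-06), and 1 fell. That P450 was Cyp2u1, named after its value was seen (-0.59, adjusted p = 0.0087). The counts were 13 and 2 adjusted over the list alone, and the list's adjusted p of 3.9e-08 became 0.0689 with an estimated correlation. Of 36 conjugation genes 12 rose, among them Gstm1 (0.62 ± 0.07, adjusted p = 0.00012) and Gstm2 (1.03 ± 0.13, adjusted p = 0.00028), with 18 higher and 1 lower adjusted over the list alone (list adjusted p = 8e-09, and 0.0689 with an estimated correlation). Of 23 NRF2 targets 9 rose, including the epoxide hydrolase gene Ephx1 (0.43 ± 0.07, adjusted p = 0.0016) and Gsta2 (0.99 ± 0.18, adjusted p = 0.0041). Adjusted over the list alone, 11 were higher and 2 lower (list adjusted p = 1.2e-08, and 0.177 with an estimated correlation).

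The other electron carriers of the microsomal P450 system changed little. None of 7 redox partners passed the threshold (1 higher adjusted over the list alone), with Cyb5a, the cytochrome b5 gene, at 0.11 ± 0.03 (adjusted p = 0.058) and Pgrmc1 at 0.07 ± 0.03 (adjusted p = 0.27; list adjusted p = 0.119). In haem metabolism the oxygenase gene Hmox1 rose by 0.63 ± 0.12 (adjusted p = 0.0047), as did the haem exporter gene Flvcr1 (0.32 ± 0.09, adjusted p = 0.042). Leaving out any of 14 of the 18 arrays ended the call of Flvcr1 (adjusted p up to 0.095, without knockout canola replicate 2), as did the mean of all its probe sets (0.10, adjusted p = 0.49). The haem list of 13 had 2 higher genes, also adjusted over the list alone, with a mean of 0.03, a median of -0.02 and adjusted p = 0.868.

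Among genes of lipid uptake and storage Lpl, which releases fatty acids from lipoproteins, rose by 1.31 ± 0.09 (2.48-fold, adjusted p = 9.1e-08), Anxa2 by 0.69 ± 0.12 (adjusted p = 0.0021), the fatty acid translocase gene Cd36 by 1.17 ± 0.23 (adjusted p = 0.0069) and Fabp4 by 0.45 ± 0.11 (adjusted p = 0.025; 0.052 without knockout canola replicate 2). Pparg, the regulator of this list and named after its value was seen, rose by 0.70 (adjusted p = 0.037). These are the 5 of 19 lipid droplet genes past the threshold (7 higher adjusted over the list alone; list adjusted p = 0.00044, and 0.321 with an estimated correlation). Of 14 genes of polyunsaturated fatty acid desaturation and elongation, Fads6 (0.45 ± 0.07, adjusted p = 0.0013), Elovl1 (0.34 ± 0.08, 0.016) and Hsd17b12 (0.20 ± 0.05, 0.039) rose, 4 being higher adjusted over the list alone (list adjusted p = 0.237). Hsd17b12 lost its call without any of 14 arrays (adjusted p up to 0.09, without knockout canola replicate 1). Among 36 PPARalpha targets Angptl4, an inhibitor of lipoprotein lipase, rose by 0.52 ± 0.12 (adjusted p = 0.021; 0.052 without knockout canola replicate 2), the 1 gene past either adjustment, also adjusted over the list alone. That list had an adjusted p of 0.0384, and 0.613 with an estimated correlation. No fatty acid synthesis gene of 26 passed, even adjusted over the list alone, with Srebf1 at -0.42 (adjusted p = 0.051) and Scd2 at 0.40 (0.074). The list was lower (median -0.13, adjusted p = 0.00994, and 0.524 with an estimated correlation). A dim probe set of Angptl4 gave -0.08, and with the mean of all probe sets Angptl4 was at 0.22 (adjusted p = 0.12), Fabp4 at 0.20 (0.12) and Anxa2 at 0.32 (0.017).

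In cholesterol synthesis and uptake 2 of 20 genes fell (3 adjusted over the list alone): the sterol carrier gene Stard4 by 0.35 ± 0.08 (adjusted p = 0.023; 0.053 without knockout canola replicate 2) and the sterol reductase gene Tm7sf2 by 0.33 ± 0.09 (adjusted p = 0.049). With the mean of all probe sets Stard4 was at -0.27 (adjusted p = 0.15). The call of Tm7sf2 ended without any of 13 arrays (adjusted p up to 0.092, without control fish/fungal replicate 1). The list's adjusted p of 0.0039 became 0.361 with an estimated correlation. Bile acid synthesis lost Cyp7b1, given before, and Cyp39a1, the 24-hydroxycholesterol hydroxylase (-0.92 ± 0.24, adjusted p = 0.035), the 2 lower genes of 14 under either adjustment, the one over all genes or adjusted over the list alone (list adjusted p = 0.509). Cyp39a1 lost its call without any of 12 arrays (adjusted p up to 0.082, without knockout canola replicate 2). Of 17 transporters of bile acids and sterols 3 rose: Slco1a4, the basolateral exporter gene Abcc3 (1.18 ± 0.16, adjusted p = 0.00044) and the bile salt pump gene Abcb11 (0.34 ± 0.08, adjusted p = 0.029). Abcb11 lost its call without any of 8 arrays (adjusted p up to 0.063, without knockout lard replicate 1). Adjusted over the list alone 5 transporters were higher and 1 lower (list adjusted p = 0.0109, and 0.321 with an estimated correlation). Among 18 lipoprotein genes Apom fell by 0.32 ± 0.07 (adjusted p = 0.012), the only one adjusted over the list alone as well (list mean 0, median -0.01, adjusted p = 0.574). None of 14 genes of glucose metabolism passed under either adjustment, over all genes or adjusted over the list alone, with Foxo1 at -0.23 (adjusted p = 0.082) and Ldha at -0.17 (0.11; list adjusted p = 0.221).

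Among stress genes Asns, the asparagine synthetase induced by the integrated stress response, rose by 1.59 ± 0.31 (3-fold, adjusted p = 0.0068), Trib3 by 0.43 ± 0.08 (adjusted p = 0.005) and the chaperone gene Dnajb9 by 0.33 ± 0.09 (adjusted p = 0.042; up to 0.084 without any of 14 arrays, highest without knockout canola replicate 1). These 3 of 22 genes became 5 adjusted over the list alone (list adjusted p = 0.0017, and 0.321 with an estimated correlation). Of 23 acute phase genes Lcn2, Orm3 (1.12 ± 0.15, adjusted p = 0.00045), the interleukin antagonist gene Il1rn (0.28 ± 0.06, 0.016) and Crp (0.16 ± 0.04, 0.048) rose. Il1rn was at 0.55 (adjusted p = 5e-04) with the mean of all probe sets. Crp lost its call without any of 14 arrays (adjusted p up to 0.1, without knockout canola replicate 1). In all 7 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.00045, and 0.321 with an estimated correlation). Of 19 cell cycle genes Ccnd1, the G1 cyclin, rose by 0.69 ± 0.10 (adjusted p = 0.00085; 3 adjusted over the list alone; list adjusted p = 0.0027, and 0.321 with an estimated correlation). Of 7 genes of fetal and regenerating liver Ly6d rose by 1.31 ± 0.33 (adjusted p = 0.031), with 3 higher and 1 lower adjusted over the list alone (list adjusted p = 0.237). Ly6d lost its call without any of 10 arrays (adjusted p up to 0.066, without knockout canola replicate 2).

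Of 18 male-biased genes 6 fell, led by the adipokine gene Serpina12 (-1.10 ± 0.19, adjusted p = 0.0028), Cyp7b1, the ferritin receptor gene Scara5 (-0.60 ± 0.13, 0.012) and the steroid dehydrogenase gene Hsd3b5 (-0.47 ± 0.10, 0.014). Adjusted over the list alone 9 were lower (list adjusted p = 3.0e-04, and 0.316 with an estimated correlation). Of 14 female-biased genes 4 rose, Cyp2b10, Cyp3a44 (0.49 ± 0.09, adjusted p = 0.0054), Atp6v0d2 (0.53 ± 0.10, 0.0069) and Gstt3 (0.89 ± 0.20, 0.014), and 5 adjusted over the list alone (list median 0.47, adjusted p = 5.8e-05, and 0.177 with an estimated correlation). Both sex-biased lists share genes with lists above: Cyp2b10 and Cyp3a44 are also among the P450s, and Cyp7b1 is in bile acid synthesis. Per1, a repressor of the circadian clock, fell by 0.43 ± 0.11 (adjusted p = 0.031), 1 of 17 clock genes (3 lower adjusted over the list alone; list adjusted p = 3.0e-04, and 0.177 with an estimated correlation). Per1 lost its call without any of 9 arrays (adjusted p up to 0.071, without knockout fish/fungal replicate 2). A dim probe set of Scara5 gave 0, and with the mean of its probe sets Scara5 was at -0.30 (adjusted p = 0.016).

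Markers of liver cell types were read in the same way, with the limit that bulk RNA does not separate cell number from expression per cell. Of 18 markers of Kupffer cells and macrophages 8 rose: the elastase gene Mmp12 by at least 1.61 ± 0.22 (3.06-fold, adjusted p = 0.00046), Itgax by 0.26 ± 0.05 (0.0067), the lysosomal gene Cd68 by 0.52 ± 0.10 (0.0069), Gpnmb by 0.51 ± 0.10 (0.0086) and, named after their values were seen, Lyz2 (0.54, 0.013), Ctss (0.38, 0.018), C1qa (0.40, 0.037) and C1qb (0.40, 0.039). Adjusted over the list alone 12 were higher (median 0.33, list adjusted p = 1.1e-10, and 0.177 with an estimated correlation). A dim probe set of Gpnmb gave -0.02. Control means of Mmp12 (3.80 to 4.14) and Timp1 (4.76 to 5.06) lay below the array medians, so their changes are lower bounds. Of 16 stellate cell and fibroblast markers Timp1 (0.36 ± 0.06, adjusted p = 0.0031) and the basement membrane gene Col4a1 (0.55 ± 0.13, 0.019) rose, 7 being higher adjusted over the list alone (list adjusted p = 3.0e-04, and 0.316 with an estimated correlation). Of 17 pericentral hepatocyte markers 4 rose: Cyp1a2 by 0.63 ± 0.11 (adjusted p = 0.0025), the ammonium transporter gene Rhbg by 0.70 ± 0.13 (0.0056), Oat by 0.42 ± 0.08 (0.0061) and Aldh1a1 by 0.28 ± 0.06 (0.012). Adjusted over the list alone 5 were higher (list adjusted p = 2.0e-04, and 0.177 with an estimated correlation).

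Other cell types gave little or no change. None of 14 periportal markers passed under either adjustment, over all genes or adjusted over the list alone (Hsd17b6 0.25, adjusted p = 0.13; Hal -0.24, 0.17; list adjusted p = 0.472), nor did any of 14 sinusoidal endothelial markers (Stab2 0.28, 0.12; Lyve1 0.35, 0.14; list adjusted p = 0.29). Of 10 lymphocyte markers Ighm, the IgM heavy chain gene, fell by 0.58 ± 0.12 (adjusted p = 0.011), the 1 lower gene adjusted over the list alone as well (list adjusted p = 0.685). The 10 other probe sets of Ighm gave -0.15 to 0.09, and with the mean of all probe sets the change was -0.09 (adjusted p = 0.24). None of 5 neutrophil markers passed under either adjustment, over all genes or adjusted over the list alone (Mpo -0.14, 0.3; list adjusted p = 0.397). Of 6 pancreatic acinar markers Cela1 fell by 0.57 ± 0.13 (adjusted p = 0.018), again the 1 lower gene adjusted over the list alone (list adjusted p = 0.0872). The lists for cholangiocytes, erythroid cells and muscle or fat had 4, 3 and 4 tested members, too few for a list test. Their leading genes were Krt23 (0.64, adjusted p = 0.09), the red cell carbonic anhydrase gene Car1 (-0.33 ± 0.09, adjusted p = 0.048) and Ckm (-0.15, 0.16). Car1 lost its call without any of 13 arrays (adjusted p up to 0.1, without knockout canola replicate 1).

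**Figure D1:**
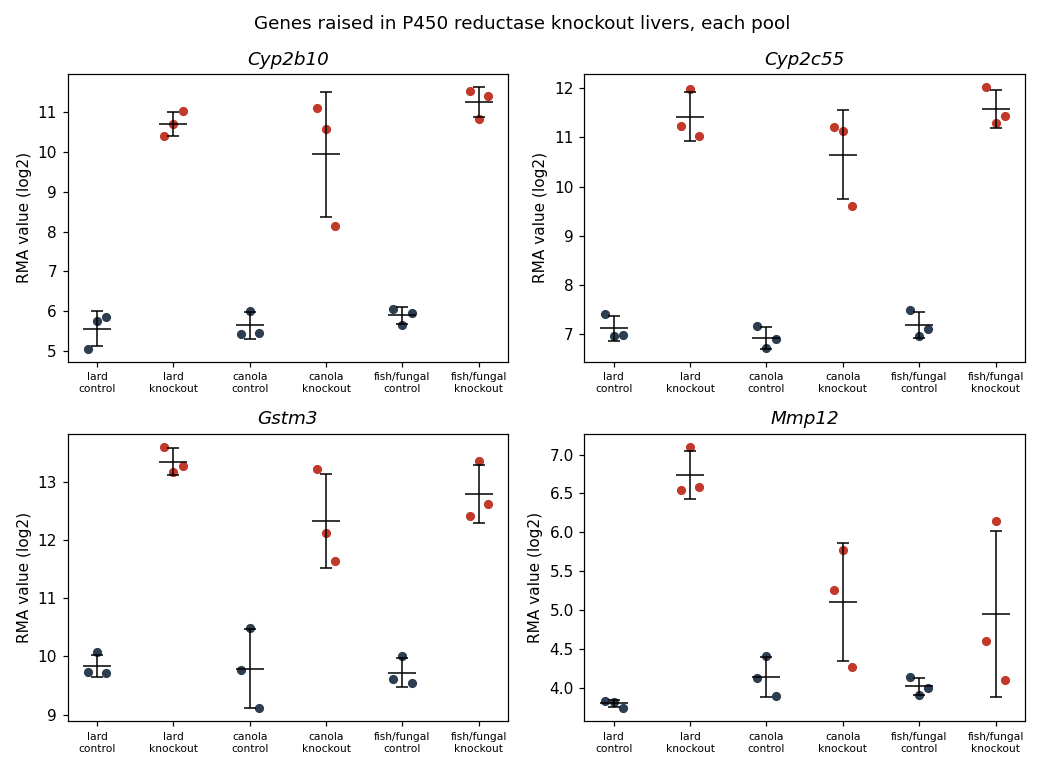
Log2 expression of Cyp2b10, Cyp2c55, Gstm3 and Mmp12 in each pool by diet, control pools dark and knockout pools red; points are pools and bars are mean ± SD (n = 3). Cyp2b10 rises from 5.57 to 10.69 on lard, while the 3 knockout canola pools spread from 8.14 to 11.08.

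The knockout effect was then read within each diet (3 pools against 3). On lard, Cyp2b10 rose by 5.12 ± 0.49 (34.7-fold, adjusted p = 4.5e-05), Cyp2c55 by 4.30 ± 0.34 (19.7-fold, 4.6e-06) and Gstm3 by 3.51 ± 0.35 (11.4-fold, 5.1e-05). The organic anion transporter gene Slc22a7 fell by 1.35 ± 0.28 (adjusted p = 0.029), Tspyl4 by 1.15 ± 0.22 (0.019) and Ighm by 0.93 ± 0.22 (0.048). Each of these falls was lost in some fits without 1 array: Slc22a7 was lost without any of the 6 (adjusted p up to 0.1, without knockout lard replicate 1), Tspyl4 without any of 5 (up to 0.095, without knockout lard replicate 3) and Ighm without any of 5 (up to 0.2, without control lard replicate 2). With the mean of all probe sets Ighm was at -0.14 (adjusted p = 0.53) and Tspyl4 at -0.61 (0.019), and Ighm was at -0.42 (0.36) without probe sets prone to cross-hybridization. In all 124 genes passed on lard, 113 higher and 11 lower (1325 at unadjusted p under 0.05). Without control lard replicates 1, 2 and 3 in turn the counts were 43, 48 and 30, and without the knockout lard replicates 53, 48 and 61. CAR and PXR targets held 14 higher genes of 26 (18 higher and 1 lower adjusted over the list alone; list adjusted p = 2.1e-26, and 0.046 with an estimated correlation). Among macrophage markers Mmp12 (at least 2.95, adjusted p = 0.0013), Lyz2 (0.96, 0.033), Cd68 (0.84, 0.032), Gpnmb (0.86, 0.03) and Itgax (0.41, 0.033) were higher, and 12 of the 18 were adjusted over the list alone (list adjusted p = 6.1e-16, and 0.0748 with an estimated correlation).

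On canola, Cyp2b10 rose by 4.28 ± 0.49 (19.5-fold, adjusted p = 6.0e-04), Cyp2c55 by 3.72 ± 0.34 (13.2-fold, 4.3e-05) and Gstm3 by 2.54 ± 0.35 (5.81-fold, 0.0049), and the glypican gene Gpc1 fell by 0.69 ± 0.11 (0.013). The other 4 of the 8 genes past the threshold, named after their values were seen, were Ces2a (1.05, adjusted p = 0.0056), Lpl (0.97, 0.0132), Rragd (0.88, 0.0464) and Golm2 (0.86, 0.0132). At unadjusted p under 0.05 there were 772 genes. Knockout canola replicate 3 had weaker changes, with Cyp2b10 at 8.14 against 5.65 ± 0.33 in controls and 11.08 and 10.57 in the other knockout canola pools, and 28 genes passed without it. The count was 5, 11 and 3 without control canola replicates 1, 2 and 3, and 4 and 3 without knockout canola replicates 1 and 2. With only the canola groups in the fit the adjusted p was 0.13 for Cyp2b10 and 0.19 for Gstm3 and Gpc1. Gpc1 lost its call in 4 of the 6 fits without 1 array (adjusted p up to 0.13, without knockout canola replicate 2). Of the CAR and PXR targets 4 were higher (19 adjusted over the list alone; list adjusted p = 1.0e-25, and 0.0506 with an estimated correlation). No macrophage marker passed, even adjusted over the list alone (list adjusted p = 0.0013, and 0.445 with an estimated correlation).

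On the fish/fungal diet, Cyp2b10 rose by 5.34 ± 0.49 (40.5-fold, adjusted p = 1.6e-05), Cyp2c55 by 4.39 ± 0.34 (21-fold, 3.0e-06) and Gstm3 by 3.07 ± 0.35 (8.42-fold, 0.00024). Obp2a, an odorant-binding lipocalin gene, fell by 2.69 ± 0.34 (6.44-fold, adjusted p = 0.001), Tmem120a by 1.77 ± 0.26 (0.0042) and the acetyltransferase gene Nat8 by 1.38 ± 0.25 (0.019). Nat8 lost its call in 3 of the 6 fits without 1 array (adjusted p up to 0.1, without control fish/fungal replicate 1) and with only the groups compared (0.09). The other 2 falls, named after their values were seen, were Wfdc12 (-1.03, adjusted p = 0.0143) and Snx17 (-0.87, 0.00327). In all 37 genes passed, 32 higher and 5 lower (959 at unadjusted p under 0.05). The count was 15, 24 and 33 without control fish/fungal replicates 1, 2 and 3, and 36, 13 and 15 without the knockout ones. Of the CAR and PXR targets 7 were higher (15 adjusted over the list alone; list adjusted p = 1.6e-24, and 0.0602 with an estimated correlation). No macrophage marker passed, even adjusted over the list alone (list adjusted p = 5.4e-05, and 0.38 with an estimated correlation).

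Knockout effects on different diets resembled each other. Across the 12578 genes, which are not independent replicates, the effects correlated at r = 0.624 for lard and canola (rho 0.421; jackknife SE over arrays 0.18), 0.638 for lard and fish/fungal (rho 0.476; 0.13) and 0.572 for canola and fish/fungal (rho 0.398; 0.14). Genes higher in the knockout on 2 diets numbered 6 for lard and canola (0.063 expected from independent lists), 17 for lard and fish/fungal (0.29) and 6 for canola and fish/fungal (0.018). These correlations compare different pools throughout.

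The next question was how the fish/fungal oil changes the liver relative to lard when the reductase is present. In control mice the largest fall was in Fads1, the delta-5 desaturase (-3.42 ± 0.26, 10.7-fold, adjusted p = 2.9e-06; 3 pools against 3). Mfsd2a, a lysophospholipid transporter, fell by 3.11 ± 0.40 (8.62-fold, 0.00056), Fasn, the fatty acid synthase, fell by 2.91 ± 0.47 (7.51-fold, 0.0039) and Fabp5 by 2.87 ± 0.41 (7.32-fold, 0.0016). The elongase gene Elovl5 fell by 2.72 ± 0.29 (9.3e-05), the farnesyl diphosphate synthase gene Fdps by 2.69 ± 0.36 (6.0e-04), the acetyl-CoA carboxylase gene Acacb fell by 2.58 ± 0.42 (0.0038), Apoa4 by 2.53 ± 0.28 (0.00014), the delta-6 desaturase gene Fads2 fell by 2.49 ± 0.27 (9.7e-05) and Rdh11 by 2.27 ± 0.26 (0.00017). Obp2a rose most (2.95 ± 0.34, 7.72-fold, adjusted p = 0.00018), followed by the metallothionein genes Mt2 (2.55 ± 0.55, 0.037) and Mt1 (2.35 ± 0.43, 0.012). A second Fads1 probe set gave -1.31, dim probe sets of Acacb and Fdps both gave 0.07, one of Msmo1 gave 0.08, and another of Mt1 gave 0.42 (adjusted p = 0.75). With the mean of all probe sets Fdps was at -1.31 (adjusted p = 0.0025), Acacb at -1.25 (0.01) and Msmo1 at -0.64 (0.0048).

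Smaller rises were those of Wfdc12 (0.93 ± 0.18, adjusted p = 0.014), Znf41-ps (0.77 ± 0.16, 0.036), Akr1c19 (0.76 ± 0.15, 0.018), Ephx1 (0.72 ± 0.12, 0.0061), Wnk4 (0.65 ± 0.15, 0.048), Zfp991 (0.65 ± 0.14, 0.045) and Rpp40 (0.58 ± 0.10, 0.0079). The 10 largest falls and Obp2a kept their calls whichever array was left out, whereas many rises did not. The highest adjusted p was 0.23 for Mt2 and 0.1 for Wfdc12 (both without control fish/fungal replicate 3), and 0.18 for Wnk4 (without control lard replicate 3). Without control lard replicate 2 it was 0.083 for Mt1, 0.1 for Akr1c19, 0.051 for Ephx1, 0.23 for Zfp991, 0.18 for Znf41-ps and 0.06 for Rpp40. With only the groups compared in the fit it was 0.083 for Mt2, 0.12 for Wfdc12, 0.063 for Zfp991 and 0.069 for Rpp40. Lard means of Znf41-ps (4.96) and Wnk4 (5.19) lay below the array medians, so their rises are lower bounds. In all 90 genes passed, 12 higher and 78 lower (3 and 40 of them at least 2-fold; 1003 genes at unadjusted p under 0.05). The count was 41 without control lard replicate 2, and 52 and 51 without control fish/fungal replicates 2 and 3. In a simulation of this comparison over 12578 genes, 52.2% of planted changes of log2 0.5, 92.5% of those of log2 1 and 100% of those of log2 2 were found.

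The falls in control mice gather in lipid synthesis. Of 20 genes of cholesterol synthesis and uptake 13 fell and all 20 did adjusted over the list alone (median -1.09, list adjusted p = 3.4e-40, and 0.00197 with an estimated correlation), led by Stard4 (-1.58 ± 0.15, adjusted p = 1.9e-05), Fdps, the sterol oxidase gene Msmo1 (-1.35 ± 0.18, 6.0e-04) and Sc5d (-1.02 ± 0.13, 0.00061). Of 26 genes of fatty acid synthesis 11 fell, and 20 adjusted over the list alone (median -1.10, list adjusted p = 6.0e-38, and 0.00468 with an estimated correlation). Of 14 genes of polyunsaturated fatty acid desaturation and elongation 6 fell, among them Elovl2 (-1.24 ± 0.11, adjusted p = 8.7e-06), and 9 adjusted over the list alone (median -0.57, list adjusted p = 3.1e-20, and 0.00197 with an estimated correlation). Of 18 lipoprotein genes Apoa4, Apoa5 (-0.35 ± 0.07, 0.027) and Apoc2 (-0.43 ± 0.09, 0.032) fell, and 5 adjusted over the list alone (list adjusted p = 4.4e-06, and 0.00315 with an estimated correlation). Apoa5 was lost in 4 of the 6 fits without 1 array (adjusted p up to 0.16, without control lard replicate 2) and with only the groups compared (0.12). Apoc2 was lost without any of the 6 arrays (up to 0.11, without control lard replicate 1). The lipid droplet list, with Apoa4 and Fabp2 (-1.08 ± 0.16, adjusted p = 0.0022) lower, had an adjusted p of 0.0716.

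Outside lipid synthesis in control mice Ccnd1 fell by 0.97 ± 0.18 (adjusted p = 0.012). Its call was lost in 3 of the 6 fits without 1 array (adjusted p up to 0.088, without control lard replicate 2). Mt1 and Mt2 were the 2 acute phase genes past the threshold (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0062, and 0.601 with an estimated correlation). PPARalpha targets had no gene past the threshold, even adjusted over the list alone, with the omega-hydroxylase gene Cyp4a14 at 2.63 ± 0.79 (adjusted p = 0.22; list adjusted p = 0.0129, and 0.707 with an estimated correlation). No CAR or PXR target and no P450 of families 1 to 3 passed (8 higher, and 5 higher with 1 lower, adjusted over the list alone; Cyp2c37 0.74 ± 0.18, adjusted p = 0.086). Those lists had an adjusted p of 5.5e-04 and 0.0098, and both 0.601 with an estimated correlation. Glucose metabolism (Ldha -0.40, adjusted p = 0.088; list 2.2e-04, and 0.224 with an estimated correlation), the stress response (Pdia4 -0.34, 0.19; list 0.0156, and 0.601) and macrophage markers (Lyz2 0.66, 0.25; list 0.0038, and 0.601) had no gene past the threshold. Leading members elsewhere were Pgrmc2 (-0.54, adjusted p = 0.087), Sult1c2 (-0.69, 0.086), Slc10a1 (-0.37, 0.074), Scp2 (-0.14, 0.45), Blvrb (0.50, 0.21), Tff3 (-1.16, 0.098), Serpina12 (-1.01, 0.3), Cyp2b9 (2.69, 0.29), Arntl (-0.49, 0.58) and Hsd17b6 (0.59, 0.099). Cell type markers gave Aldh1a1 (0.29, 0.4), Krt23 (1.15, 0.24), Timp1 (0.19, 0.74), Stab1 (-0.26, 0.59), Ighm (-0.76, 0.17), Csf3r (0.17, 0.77), Car1 (0.35, 0.57), Prss2 (0.08, 0.9) and Car3 (0.12, 0.7).

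The same diets were compared in knockout mice to ask whether the response needs the reductase. Mfsd2a fell by 3.41 ± 0.40 (10.6-fold, adjusted p = 0.00056; 3 pools against 3), Fads1 fell by 3.37 ± 0.26 (10.3-fold, 3.8e-06), Apoa4 by 2.60 ± 0.28 (6.05-fold, 3.0e-04) and Fdps by 2.55 ± 0.36 (5.86-fold, 0.002). Fasn fell by 2.48 ± 0.47 (0.024), Acacb fell by 2.25 ± 0.42 (0.022), Fads2 by 2.15 ± 0.27 (0.001), the isoprenoid isomerase gene Idi1 fell by 2.06 ± 0.31 (0.0047), Elovl5 fell by 1.95 ± 0.29 (0.0036) and the tubulin gene Tubb2a by 1.78 ± 0.34 (0.026). Fasn and Acacb each lost their call in 4 of the 6 fits without 1 array (adjusted p up to 0.17 and 0.12, both without knockout lard replicate 1). Without knockout lard replicate 1 the adjusted p was 0.053 for Idi1, and without knockout fish/fungal replicate 3 it was 0.16 for Tubb2a. With only the groups compared in the fit it was 0.17 for Fasn, 0.13 for Acacb, 0.085 for Idi1, 0.06 for Fdps, 0.054 for Fads2 and 0.072 to 0.088 for the 5 rises given next. The other probe set of Tubb2a gave -0.58 (adjusted p = 0.55). The 5 rises were Mt1 (2.22 ± 0.43, 0.029), Serpinb1a (1.65 ± 0.35, 0.048), Gpcpd1 (1.14 ± 0.22, 0.029), Adam11 (0.84 ± 0.15, 0.021) and the carbonic anhydrase gene Car14 (0.62 ± 0.12, 0.023). The calls of all 5 were lost in some fits without 1 array: without knockout lard replicate 1 the adjusted p was 0.19 for Mt1, 0.27 for Serpinb1a, 0.12 for Adam11 and 0.11 for Car14, and without knockout fish/fungal replicate 3 it was 0.18 for Gpcpd1. Over the fits without 1 array the rises ran from 0.73 to 0.983 for Adam11, 0.596 to 0.668 for Car14 and 0.916 to 1.258 for Gpcpd1. Over all alternatives that of Serpinb1a ran from 1.351 to 1.971. A second Fads1 probe set gave -0.87, dim ones of Acacb and Fdps gave 0.05 and 0.01, and another of Mt1 gave 0.16 (adjusted p = 0.95). With the mean of all probe sets Fads1 was at -2.12 (adjusted p = 1e-05), Fdps at -1.27 (0.006), and Acacb at -1.10 (0.033), and Tubb2a and Mt1 lost their calls (0.098 and 0.095). In all 58 genes passed, 5 higher and 53 lower (3 and 25 at least 2-fold; 1076 at unadjusted p under 0.05). The count was 12 and 34 without knockout lard replicates 1 and 3, and 32, 116 and 19 without knockout fish/fungal replicates 1, 2 and 3.

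In knockout mice 9 of 20 cholesterol genes fell (15 adjusted over the list alone; median -0.99, list adjusted p = 7.8e-31, and 0.00739 with an estimated correlation), led by Stard4 (-1.15 ± 0.15, adjusted p = 0.0011; 0.059 with only the groups compared in the fit) and the lanosterol demethylase gene Cyp51 (-1.70 ± 0.23, 0.0017). Of 26 fatty acid synthesis genes 7 fell, including Rdh11 (-1.63 ± 0.26, 0.0067; 0.062 without knockout lard replicate 1, 0.054 with only the groups compared), and 19 adjusted over the list alone (median -0.86, list adjusted p = 6.5e-25, and 0.0304 with an estimated correlation). Of the desaturation and elongation genes 4 of 14 fell, with Elovl2 at -0.78 ± 0.11 (0.0017), and 9 adjusted over the list alone (median -0.54, list adjusted p = 6.6e-12, and 0.0187 with an estimated correlation). Apoa4 and Apoc2 (-0.67 ± 0.09, 0.0016) were the 2 lower lipoprotein genes of 18, also adjusted over the list alone (list adjusted p = 0.0164, and 0.119 with an estimated correlation). The replication factor gene Mcm6 fell by 0.94 ± 0.16 (adjusted p = 0.0097; 0.074 without knockout fish/fungal replicate 3, 0.15 with only the groups compared), with 1 cell cycle gene higher and 7 lower adjusted over the list alone (list adjusted p = 6.9e-06, and 0.281 with an estimated correlation). Other list members that fell were Fabp2 (-0.86, 0.023; 0.15 without knockout fish/fungal replicate 3), Serpina12 (-1.58 ± 0.33, 0.042; 0.26 without knockout lard replicate 1), the bile acid transporter gene Slc51b (-0.68, 0.033; 0.19 without knockout lard replicate 1) and Gsta3 (-0.45, 0.04; 0.25 without knockout fish/fungal replicate 3). With only the groups compared they had 0.085, 0.072, 0.27 and 0.19. Of the 6 fits without 1 array, 3 ended the call of Fabp2 and 5 that of Gsta3. Mmp12 was at -1.79 ± 0.39 (adjusted p = 0.051), a lower bound in size since its mean was 4.95 on fish/fungal oil, and the macrophage list had an adjusted p of 0.0376, and 0.672 with an estimated correlation.

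Leading members that did not pass in knockout mice were Me1 (-2.16, adjusted p = 0.11), Cyb5r3 (-0.62, 0.11), Cyp2g1 (0.91, 0.34), Sult5a1 (0.66, 0.18), Cyp8b1 (0.96, 0.097), Eci2 (0.33, 0.53), Pdk4 (-1.24, 0.54), Hmox2 (0.15, 0.72), Ldha (-0.32, 0.26), Trib3 (0.49, 0.19), Cd24a (-0.40, 0.5), Cux2 (0.29, 0.43) and Clock (-0.36, 0.39). Cell type markers gave Lect2 (-0.31, adjusted p = 0.4), Hsd17b6 (0.53, 0.19), Epcam (0.15, 0.82), Timp1 (-0.40, 0.18), Stab1 (-0.36, 0.3), Jchain (0.60, 0.52), Mpo (0.18, 0.78), Car1 (0.38, 0.48), Cela2a (0.35, 0.62) and Ckm (0.21, 0.54). The fall in Fads1, Fasn, Mfsd2a and their group was shared by both genotypes: 34 genes were lower in both against 0.33 expected from independent lists, and Mt1 was the 1 gene higher in both. Of the 90 genes called in control mice 88 had the same sign in knockout mice, and 55 of the 58 called in knockout mice had it in controls. Across all tested genes the effects in the genotypes correlated at r = 0.625 (rho 0.422; jackknife SE over arrays 0.099). Averaged over genotypes, 292 genes passed the threshold.

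**Figure D2:**
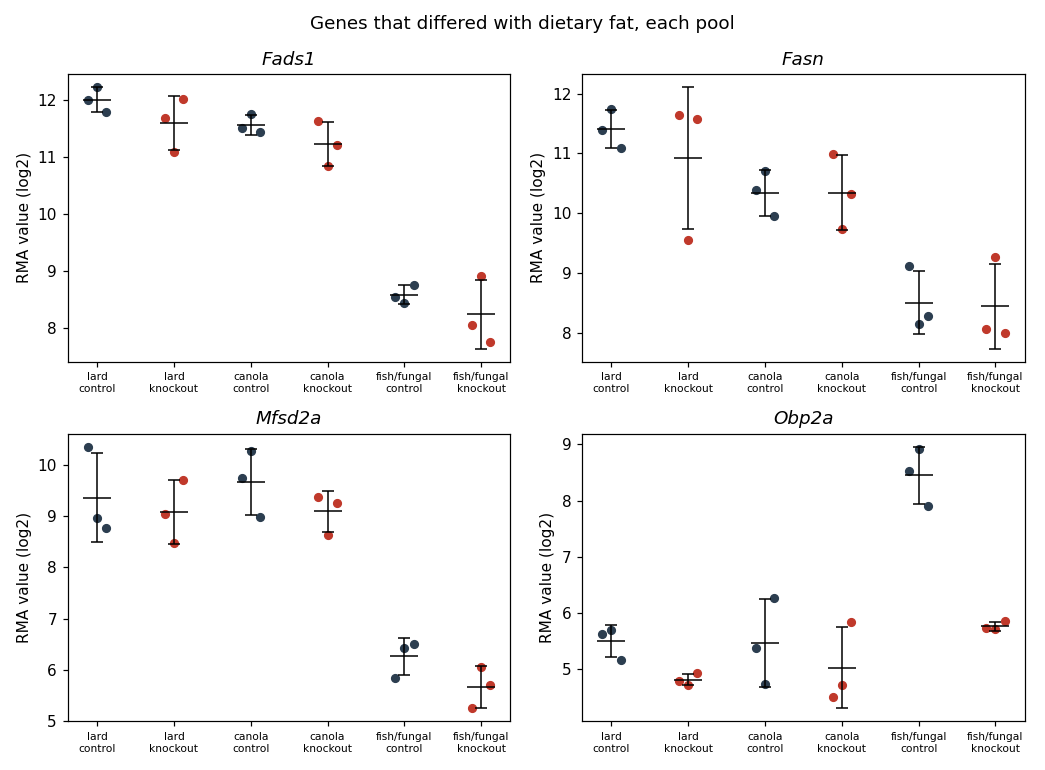
Log2 expression of Fads1, Fasn, Mfsd2a and Obp2a in each pool by diet, control pools dark and knockout pools red; points are pools and bars are mean ± SD (n = 3). Fads1 falls from 12.00 on lard to 8.58 on fish/fungal oil in controls and from 11.59 to 8.23 in knockouts, and Obp2a stands at 5.50 on lard and 8.45 on fish/fungal oil in controls and at 4.81 and 5.76 in knockouts.

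Fish/fungal oil was also compared with canola oil, to see which differences do not rest on the lard pools. Both comparisons use the same fish/fungal pools of each genotype, so they are not independent of each other. A peculiarity of those pools would appear in both. In control mice Mfsd2a fell by 3.41 ± 0.40 (10.6-fold, adjusted p = 0.00024; 3 pools against 3), Fads1 by 2.99 ± 0.26 (7.93-fold, 2.4e-05) and Apoa4 fell by 2.78 ± 0.28 (6.88-fold, 0.00011), while Obp2a rose by 2.99 ± 0.34 (7.92-fold, 0.00024), Wfdc12 by 0.99 ± 0.18 (0.017) and Wnk4 by 0.73 ± 0.15 (0.039). Wfdc12 had an adjusted p of 0.1 without control fish/fungal replicate 3 and 0.17 with only the groups compared, and Wnk4 lost its call without any of the 6 arrays (up to 0.2, without control canola replicate 2). The rise of Wnk4 is a lower bound, since its canola mean was 5.11. The other 2 rises, named after their values were seen, were Car14 (0.69, adjusted p = 0.0118) and Itih3 (0.45, 0.027). In all 33 genes passed, 5 higher and 28 lower (826 at unadjusted p under 0.05). The count was 21 and 19 without control canola replicates 2 and 3. Cholesterol genes lost 5 of 20, which are Fdps, Idi1, Stard4, Insig1 and Msmo1 (16 adjusted over the list alone; list adjusted p = 6.6e-32, and 0.00252 with an estimated correlation). Fatty acid synthesis lost 4 of 26 (16 adjusted over the list alone; list adjusted p = 1.3e-25, and 0.0207 with an estimated correlation), desaturation and elongation 4 of 14 (9 adjusted over the list alone; 2.0e-20, and 0.00252), and lipoproteins 3 of 18, Apoa4, Apoa5 and Apoc2 (3 adjusted over the list alone; 1.7e-06, and 0.00252).

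In knockout mice Mfsd2a fell by 3.42 ± 0.40 (10.7-fold, adjusted p = 0.00054; 3 pools against 3), Fads1 by 3.00 ± 0.26 (7.99-fold, 2.3e-05) and Apoa4 by 2.63 ± 0.28 (6.18-fold, 0.00025), and Lpl rose by 1.13 ± 0.15 (2.19-fold, 0.0024), Fam25c by 0.95 ± 0.18 (0.048) and Adam11 by 0.84 ± 0.15 (0.038). Fam25c lost its call in 5 of the 6 fits without 1 array (adjusted p up to 0.3, without knockout fish/fungal replicate 1). Adam11 lost its call in 4 of the 6 (up to 0.23, without knockout canola replicate 1). Fads1 was at -1.889 (adjusted p = 5.5e-05) with the mean of all probe sets. With only the groups compared in the fit the adjusted p was 0.051 for Lpl, 0.31 for Fam25c and 0.14 for Adam11. The remaining rise, named after its value was seen, was Car14 (0.66, adjusted p = 0.0265). In all 20 genes passed, 4 higher and 16 lower (745 at unadjusted p under 0.05). The count was 7 and 5 without knockout canola replicates 1 and 3, and 8 and 6 without knockout fish/fungal replicates 1 and 3. Lower genes were Fdps, Stard4 and Tm7sf2 of 20 in cholesterol synthesis (14 adjusted over the list alone; list adjusted p = 7.7e-20, and 0.0229 with an estimated correlation), 3 of 26 in fatty acid synthesis (15 adjusted over the list alone; 6.1e-22, and 0.0334), 4 of 14 in desaturation and elongation (4 adjusted over the list alone; 2.5e-11, and 0.0229) and 2 of 18 lipoprotein genes (2 adjusted over the list alone; 0.0018, and 0.0334). Both genotypes shared 14 lower genes against 0.036 expected from independent lists. Of the 33 control genes 31 had the same sign in knockouts, and all 20 knockout genes had it in controls. The effects correlated at r = 0.578 across genes (rho 0.347; jackknife SE over arrays 0.064). Averaged over genotypes, 124 genes passed.

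Canola oil against lard gave no gene past the threshold in either genotype. With limma 579 genes in controls and 607 in knockouts had an unadjusted p under 0.05 against 629 by chance, and the smallest adjusted p was 0.346 and 0.419. limma on the 2 control groups alone gave 2 genes, and limma with array weights or without the intensity trend gave 0. In simulations over 12578 genes, 59.7% of planted changes of log2 0.5 and 92.5% of those of log2 1 were found in controls, and 52.2% and 92.5% in knockouts. Cyp4a14 was at 3.09 in controls (adjusted p = 0.996) and 2.45 in knockouts (0.821). The list test with preset correlation called 9 lists in controls and 8 in knockouts, but none held with an estimated correlation, where the smallest adjusted p was 0.46 and 0.243. Fatty acid synthesis genes had a median of -0.33 in controls (0.46 with an estimated correlation), and macrophage markers one of -0.38 in knockouts (9 lower adjusted over the list alone, 0.243 with an estimated correlation). The effects correlated at r = 0.349 across genes (rho 0.232; jackknife SE over arrays 0.19).

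The last question was whether the knockout effect depends on the diet. limma's F test of the interaction called 0 genes (242 at unadjusted p under 0.05, smallest adjusted p = 0.52), and each pair of diets also gave 0 (305, 279 and 241 at unadjusted p under 0.05 for fish/fungal against lard, fish/fungal against canola, and canola against lard). Each of these counts lay below the 629 expected by chance, so the p-values of these tests ran high. limma with array weights or without the intensity trend also called 0. Gpc1 had the smallest p, with knockout effects of -0.58 on lard, -0.69 on canola and 0.17 on fish/fungal oil (adjusted p = 0.52). For the next genes the adjusted p was 1: the matricellular gene Ccn1 (0.78, 0.30 and -0.52 on the diets in that order), Obp2a (-0.69, -0.44 and -2.69), Lpl (1.06, 0.97 and 1.90), Wfdc12 (-0.07, 0.03 and -1.03), Sprr1a (1.94, 0.47 and 0.10), Susd1 (0.17, -0.23 and 0.41), Rlf (-0.01, 0.28 and -0.42), Gpr137b (0.76, 0.18 and 0.14) and Grasp (0.22, 0.02 and -0.32). Control means of Sprr1a (4.57 to 4.93) lay below the array medians, so its effects are lower bounds and their differences are uncertain. The knockout lard mean of Obp2a also lay below them, so its fall on lard is a lower bound and its difference from the other diets is uncertain. Without control fish/fungal replicate 1 Ccn1 passed (adjusted p = 0.0025), and without control fish/fungal replicate 2 Wfdc12 did (0.0014). In a simulation over 12578 genes, 23.9% of planted interactions of log2 0.5, 83.6% of log2 1 and 98.5% of log2 2 were found. The simulated genes were drawn independently of each other, so the shares found in the real arrays may be lower. Many interactions were planted together, which eases the Benjamini-Hochberg adjustment, so a few real ones would also be found less often. A gene such as Obp2a, called in 1 genotype and not in the other, is therefore not shown to respond differently.

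**Figure D3:**
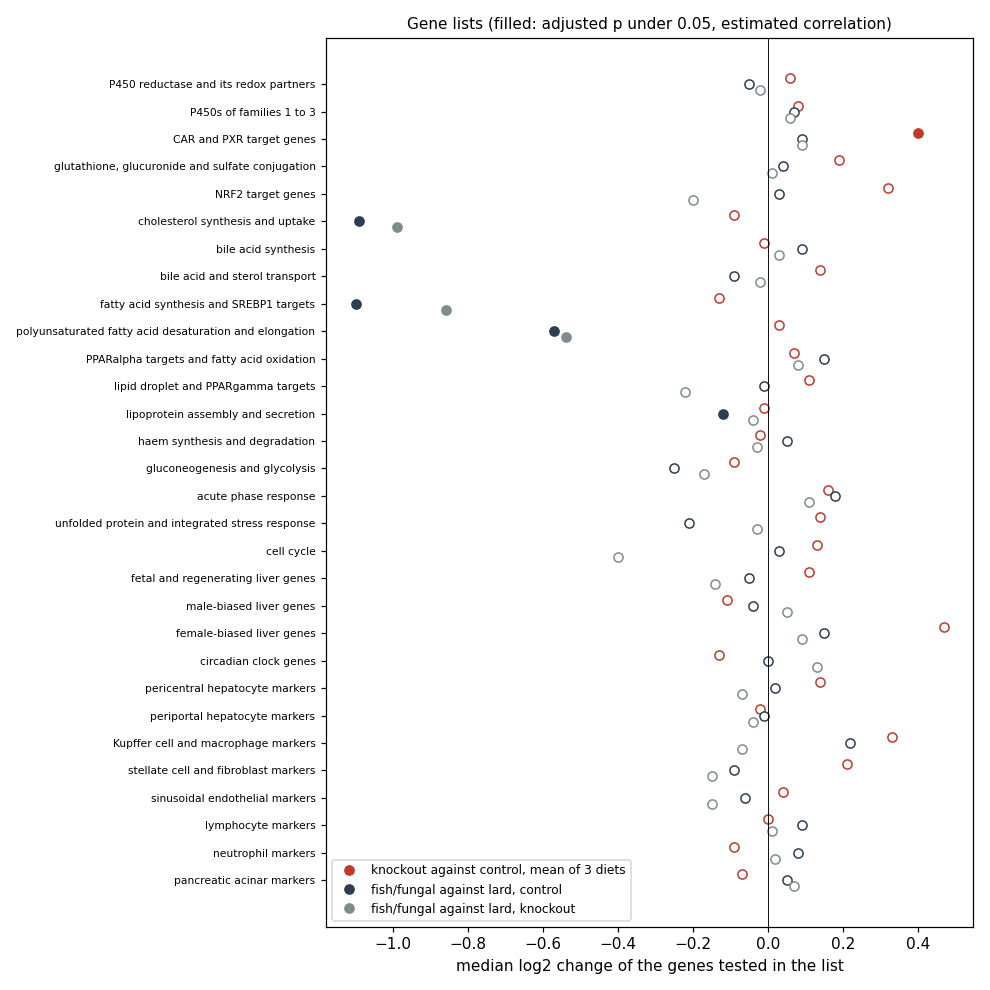
Median log2 change of each tested gene list for the knockout averaged over diets and for fish/fungal oil against lard in control and in knockout mice; filled points have an adjusted p under 0.05 with an estimated correlation. CAR and PXR targets stand at 0.40 with knockout, and cholesterol genes at -1.09 and -0.99 with fish/fungal oil.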

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

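The tests of the macrophage pattern, including those without Mmp12, the test for control RNA in the weak pool and the fractions on the log2 scale were chosen only after the result was seen. The tests of RNA quality and of a swapped array were written before.

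The mean of the 18 macrophage markers was higher in knockout livers by 0.67 on lard, 0.23 on canola and 0.26 on fish/fungal oil (mean 0.39, exact permutation p = 0.0042 within diets; 0.32 and exact p = 0.006 without Mmp12). A lower share of hepatocytes in the knockout pools could raise every non-hepatocyte marker, and the 30 endothelial and stellate markers were also higher by 0.15 (exact p = 0.021). Macrophage markers exceeded them by 0.24 (exact p = 0.0088; 0.17 and exact p = 0.043 without Mmp12), which argues against it as the whole cause of the mean over diets, but on canola the excess was 0.06. More macrophages of every kind could raise the group of Gpnmb, Trem2, Mmp12, Itgax and Cd9 (0.51) and the resident group of Clec4f, Cd5l, Marco, Timd4 and Vsig4 (0.26) alike, and their difference of 0.25 (exact p = 0.091) cannot tell; it came from Mmp12, without which it was -0.03 (exact p = 0.81). The weak knockout canola pool could have left lard standing out, where the effect exceeded the mean of the other diets by 0.42 (permutation p = 0.025), but without that pool the excess was 0.40 (permutation p = 0.039), and without Mmp12 it was 0.33 with and 0.32 without the pool (permutation p = 0.063 and 0.094), which argues against the pool as its cause and leaves open whether lard stands out beyond Mmp12.

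The array labelled knockout canola replicate 3 lay nearer the controls than the other pools of its group. Over 28 genes that rose with knockout elsewhere its median fraction of the way from control to knockout level was 0.171 on the linear scale (95% bootstrap interval 0.0954 to 0.267), against 0.95 and 0.781 in the other knockout canola pools, and 0.281 on the log2 scale (0.175 to 0.485), against 0.985 and 0.894, while over 26 genes that fell it was 0.0449 (-0.101 to 0.145), and -0.00552 on the log2 scale (-0.108 to 0.11). Poor RNA could blur a pool, but its 3' minus 5' difference was 0.62 for Actb (0.54 to 1.08 in the other 17 arrays) and -0.05 for Gapdh (-0.15 to 0.19), which argues against it. A swap with a control canola array would put that array near the knockout level, and over the rising genes the highest fraction among those arrays was 0.106 (0.201 on the log2 scale), which argues against it, although over the falling genes control canola replicate 2 stood at 0.541 (0.143 to 0.753) and those arrays spread from -0.436 upwards. RNA of control mice in the pool may account for it, yet a fraction of 0.171 cannot tell such mixing from mice whose genes were less changed, and no biological explanation was tested. The bootstrap intervals resample genes within a single array as if independent and leave out the spread between pools.

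The knockout effect on whole lists differed between diets in the preset list test, with medians of gene differences as follows. Between fish/fungal oil and lard they were -0.23 for NRF2 targets, 0.13 for cholesterol synthesis, 0.25 for fatty acid synthesis, 0.25 for desaturation and elongation, 0.18 for the unfolded protein response, -0.26 for the cell cycle and -0.32 for Kupffer cell and macrophage markers. Between fish/fungal and canola oil they were 0.16 for cholesterol synthesis, 0.14 for desaturation and elongation, 0.06 for lipid droplet genes and -0.15 for stellate cell markers. Between canola oil and lard they were -0.14 for CAR and PXR targets, -0.05 for conjugation, -0.23 for NRF2 targets, -0.05 for PPARalpha targets, -0.22 for lipid droplet genes, -0.27 for the cell cycle, -0.19 for female-biased genes and -0.34 for macrophage markers. With an estimated correlation, or with fry, 0 of these held. Without knockout canola replicate 3 the preset list test lost most of its calls between canola oil and lard. Shuffling diets within genotypes gave at least as many lists in 56, 87 and 49 of 100 draws (7, 4 and 8 lists in the real order, up to 18, 16 and 16 in others).

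Probe sets without a gene name here also carried signal. Of 2816 tested, 55 passed the threshold for the averaged knockout effect (43 higher and 12 lower), 4 for knockout on lard, 1 for knockout on fish/fungal oil, 5 for fish/fungal oil against lard in controls and 1 for fish/fungal against canola oil in controls.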

How the results depend on the processing

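The fit with 2 within-group components, the list tests without knockout canola replicate 3 and the correlations without each array were chosen only after the result was seen. No result reversed in any alternative. The 152 results for named genes, each taken through its alternatives, kept their direction and their side of the threshold in 2970 fits and lost the call in 371. Arrays read signal above background only for bright genes, and dim probe sets of called genes often showed no change. Except where fewer arrays or genes in a fit are the reason, the cause was not tested.

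Leaving out each array in turn moved the counts of genes, which ran from 371 to 698 for the averaged knockout effect (575 with all arrays), 30 to 61 on lard (124), 3 to 28 on canola (8) and 13 to 36 on fish/fungal oil (37). Fish/fungal oil against lard ran from 41 to 67 in controls (90) and 12 to 116 in knockouts (58), fish/fungal against canola oil from 19 to 25 in controls (33) and 5 to 30 in knockouts (20), canola oil against lard stayed at 0 and the interaction ran from 0 to 1. Correlations ran from 0.499 to 0.674, 0.538 to 0.68 and 0.438 to 0.607 for knockout effects (lard with canola, lard with fish/fungal, canola with fish/fungal). For diet effects they ran from 0.508 to 0.633, 0.497 to 0.561 and 0.213 to 0.397 (fish/fungal with lard, fish/fungal with canola, canola with lard). Of the named genes 58 of 71 kept their call for the averaged knockout effect whichever array was left out, 16 of 28 for fish/fungal oil against lard in controls and 10 of 25 in knockouts.

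With 2 within-group components as covariates, a circular step because they come from the residuals, counts rose to 1461 for the averaged knockout effect, 422, 39 and 125 on lard, canola and fish/fungal oil, 253 and 183 for fish/fungal oil against lard in controls and knockouts, and 100 and 55 against canola. Array weights gave 90 for knockout on canola, 50 for fish/fungal against canola in controls and 30 for fish/fungal against lard in knockouts. With only the groups compared in the fit, and so fewer arrays for the spread, counts were 1 and 22 for knockout on canola and fish/fungal oil, 2 for canola against lard in controls, and 12 and 10 for fish/fungal oil against lard and canola in knockouts. The filter at the 75th percentile gave 70 for knockout on lard, the mean of all probe sets 24 for knockout on fish/fungal oil, and median centring 50 for fish/fungal against canola in controls. The correlation over only called genes was 0.887, 0.855 and 0.887 for the knockout effects and 0.932 and 0.925 for fish/fungal oil against lard and canola. Those genes were called on a mean that includes the effects correlated, also a circular step, which raises r. With no filter the correlation over all genes for fish/fungal oil against canola was 0.51. For canola against lard the correlation over called genes was not run, because 0 genes passed.

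The labels do not say that replicate numbers pair arrays, and over all groups the data do not pair them: 16 of 45 same-numbered pairs correlated above 0.1 (range -0.40 to 0.46) and 6 of 18 arrays lay closest to one of their own number. All 3 pairs did so between knockout lard and knockout canola (0.17, 0.23 and 0.19), where the count stayed at 0 with a block, and between knockout lard and control canola (0.15, 0.22 and 0.16). A replicate block moved the count for fish/fungal against canola oil in knockouts to 13 and no other count by more than 1.5 times.

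Lists past the threshold depended on the list test. With an estimated correlation (and with fry) the averaged knockout effect had 1 (12) instead of 18, knockout on lard 1 (6) instead of 16, on canola 0 (2) instead of 15 and on fish/fungal oil 0 (2) instead of 14. Fish/fungal oil against lard had 4 (4) instead of 11 in controls and 3 (4) instead of 14 in knockouts, against canola 4 (4) instead of 10 and 4 (4) instead of 11, and canola against lard 0 (0) instead of 9 and 8. The interactions had 0 (0) instead of 7, 4 and 8. Without knockout canola replicate 3 the last became 1, and no other list count moved by more than 1.5 times.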

Other observations

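Genes in the next 2 paragraphs, and the tests of clock phase, were chosen only after the result was seen. The test of RNA quality was written before.

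A few called genes outside the fixed lists are given as single genes; no list of interferon or retinoic acid targets was tested. For the averaged knockout effect Ubd, which encodes a ubiquitin-like modifier, was higher by 1.27 (adjusted p = 0.00079), the interferon-inducible Ifi27l2b by 0.71 (3.7e-05), Usp18, which removes the ISG15 tag from proteins, by 0.62 (0.00022), the chemokine gene Cxcl10 by 0.66 (0.0063) and the adhesion molecule gene Icam1 by 0.73 (0.00086). The interaction test called none of Ubd, Ifi27l2b, Usp18, Cxcl10 and Icam1 (adjusted p = 1 each). Control means of Ubd on lard (4.99) and fish/fungal oil (4.885) lay below the array medians, so its change is a lower bound.

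Beside Cyp26a1 (1.42), Rarb, the retinoic acid receptor gene induced by its own ligand, was higher by 0.71 (adjusted p = 0.0018) and Rarres1 by 0.71 (0.0018); control means of Rarb on canola (5.111) and fish/fungal oil (5.051) lay below the array medians, so its change is a lower bound. Inhbe, an activin subunit gene induced with Asns (1.59) and Trib3 (0.43) in amino acid stress, was higher by 0.76 (adjusted p = 0.0235). The drug efflux pump gene Abcb1a was higher by 1.23 (adjusted p = 0.00019), with 1.98 on lard (0.0013), 1.06 on canola (0.257) and 0.65 on fish/fungal oil (0.568).

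Genes of fatty acid synthesis varied between pools of 1 group, with standard deviations of the list mean from 0.07 to 0.43. The list mean was 10.48, 10.09 and 9.15 on lard, canola and fish/fungal oil in controls and 10.20, 9.98 and 9.14 in knockouts. Differences in RNA quality could produce such variation, but over 18 arrays the within-group deviations gave r = 0.32 (permutation p = 0.34, adjusted p over the 2 relations 0.34; rho 0.24, permutation p = 0.43; r = 0.21 without the 2 farthest arrays), which cannot tell. Clock phase when the livers were taken may matter, and the clock score gave r = 0.43 (permutation p = 0.12, adjusted p = 0.24; rho 0.41, permutation p = 0.13; r = 0.32 without the 2 farthest), which cannot tell either. With the clock score in the fit, fish/fungal oil against lard went from -1.33 ± 0.23 to -1.36 ± 0.21 in controls and from -1.06 ± 0.23 to -1.16 ± 0.22 in knockouts.

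Labels were split anew to ask how often other groupings give as much. For the averaged knockout effect 1 of 100 splits, the real one, reached 575 genes (highest other 320), and 3 of 100 reached 18 lists (highest other 18, median 8), so the preset list test calls many lists with shuffled labels. For correlations of knockout effects 2, 1 and 1 of 100 splits reached the real values (0.624, 0.638 and 0.572; highest others 0.624, 0.488 and 0.47), and for diet effects 1 of 34 each (0.625, 0.578 and 0.349; highest others 0.418, 0.512 and 0.321). Each diet was split on its own, so a draw could keep the real grouping of lard and canola pools and change only the fish/fungal pools. Such a draw gives the real value again, and the other 0.624 may be one. For the interaction all 100 draws reached the real count of 0 genes (highest other 7). Any draw must reach a count of 0, so this outcome was fixed in advance and tests nothing. Pairs of groups allow only 10 splits, which cannot go under 0.1. Counts of genes were reached by 1 split each for knockout on lard (124; highest other 0), canola (8; 6) and fish/fungal oil (37; 0), for fish/fungal oil against lard (90; 0) and canola (33; 0) in controls, and for the same pairs in knockouts (58; 0, and 20; 1). Canola against lard, at 0 genes, was reached by all 10 in controls and in knockouts (highest other 1 in both), which was likewise fixed in advance. Counts of lists were reached by 2, 1 and 1 splits for knockout on lard, canola and fish/fungal oil (16, 15 and 14; highest others 17, 13 and 8). In controls they were reached by 1, 3 and 4 splits for fish/fungal against lard, fish/fungal against canola, and canola against lard (11, 10 and 9; highest others 10, 13 and 10). In knockouts they were reached by 1, 2 and 6 splits (14, 11 and 8; highest others 13, 12 and 15).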
